A study of Homo sapiens with 23 samples.

How the data were processed

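RNA was sequenced from 4 human multiple myeloma cell lines, H929, MM1S, OPM2 and RPMI-8226, each with an induced guide RNA against IRF4 or a guide named EV in the labels. The guides were expressed during 48 hours of doxycycline. The sequence of the IRF4 guide and the meaning of EV were not given in the sources used here. The 23 libraries formed 8 groups of 3, except the MM1S EV group with 2 libraries (replicates 2 and 3). Per the labels, total RNA was purified on RNeasy Plus Mini columns and libraries were made with a TruSeq RNA kit. The labels did not say whether replicates were separate cultures, so the p-values measured the spread between these samples, which may be technical.

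The authors deposited raw counts per Entrez gene for all 23 libraries in a single table of 28395 genes. The deposited log2 RPKM values, 1 set per library, covered 16220 genes, which were exactly those above 0.50 CPM (counts scaled to a common library total) in at least 2 libraries. Their medians per library, once gene length was accounted for, lay within 0.0223 of each other against 0.320 for log2 CPM, as after a quantile normalisation by the authors. Per the submitters' processing notes the tools were Subread, featureCounts and limma on the GRCh38 (hg38) genome, with no versions or settings. Whether reads were counted by strand was not given in the sources used here, so overlapping genes and close paralogs (HLA, IFIT and IFITM genes) carry that uncertainty. Coordinates came from a RefSeq table of the same build.

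Library totals ran from 6907390 to 28486960 counts, and the 10 most abundant genes took 3.49 to 5.44% of a library. Genes without a symbol, 490 in number, took 0.110 to 0.292% and stayed in the fit. Library pairs within a group had Pearson r from 0.988 to 0.995 across genes on log2 CPM (22 pairs, genes not being independent replicates). Squared differences within these pairs were 3.47 to 25.3 times those that counting error alone gives (chi-square per gene).

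Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group, which left 16468, and scaled by trimmed mean of M-values factors (TMM, 0.914 to 1.08). A single robust quasi-likelihood model with a mean per group gave the contrast IRF4 guide minus EV guide in each line, the average of the 4 contrasts with equal weights, and an F test with 3 degrees of freedom of the difference between lines. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Genes called the same way in all 4 lines were counted as the intersection of the calls. Each gene's error is the standard error (SE) of its log2 fold change, taken as the size of the change over the square root of F. Levels are TMM-normalised CPM with the standard deviation (SD) over libraries.

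Ratios against a group at 0 counts are lower bounds, computed with a floor of 3 counts over the group and written "at least". Those against groups with 1 to 3 counts come with a 95% counting interval. Both cover counting error only. Of the genes tested, 2761 had a group at 0 counts and 1541 a whole line at 0. The latter cannot be called on the average, where the model has no usable error for them, but 960 of them were called in a line.

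Before the data were examined, the comparisons, tests, alternatives, 31 gene lists and the rule for naming genes were fixed. The lists covered pro-apoptotic and pro-survival BCL2 family members, caspases and death receptors, plasma cell identity, the B cell programme, MHC class I presentation, MHC class II, MYC targets and nucleolus, G1/S and DNA replication, G2/M and mitosis, the unfolded protein response, the ATF4 and amino acid response, sterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, interferon-stimulated genes, interferon regulatory factors, NF-kB targets, p53 targets, the proteasome, lysosome and autophagy, adhesion and homing, cytokine receptors and signalling, immediate early genes, cytosolic heat shock, genes tied to IRF4 in myeloma, and oncogenes that mark subgroups of myeloma lines (lines by oncogene). Markers of T and NK cells, myeloid cells, stromal and epithelial cells, and erythroid cells and megakaryocytes were included as cells a myeloma culture should lack. All 591 list entries matched the count table by symbol, and 30 lists had at least 5 tested members. Lists were tested with camera (preset correlation 0.010 between genes), adjusted over the lists of a contrast, and again with a correlation estimated per list and with fry.

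The named genes were IRF4, BMF, BCL2L11, MYC, PRDM1, KLF2 and the tested members of the BCL2 family lists; the 12 largest rises and 12 largest falls on the average among genes called the same way in all 4 lines; the 5 largest rises and 5 largest falls of each line with no overlap between the groups; the 8 genes with the smallest p of the difference between lines; up to 4 called members per list with the smallest adjusted p; and the oncogenes that mark lines, for their levels. Genes ranked by change needed a mean log2 CPM of at least 1 and a symbol other than those of uncharacterised, non-coding or microRNA genes. The text names a selection of these, and some that met the rule are not reported here. Any gene outside the rule is said to have been chosen after its values were seen.

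After removal of group means, libraries of OPM2 with the same replicate number correlated at 0.183, 0.144 and 0.175 across genes, all over 0.100 and all higher than with other numbers. The numbers were therefore taken to pair the OPM2 samples. In the other lines the own number also correlated best, but not every pair was over 0.100. Results with the replicate number within each line as a block are given beside OPM2 results whose calls it changed. For the other lines they are given only in part.

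On simulated counts with the spread and depth of these libraries (16163 genes run), changes of 1.5-fold, 2-fold and 4-fold were recovered at 49.1 to 70.2%, 90.9 to 97.0% and 96.1 to 100% in single lines and at 89.5 to 100% on the average. The test of the difference between lines recovered 40.3, 87.1 and 98.5% of changes placed in H929 alone. False calls were 0.0127 to 0.127% of 15763 unchanged genes. Changes were placed in a small part of the genes, all with counts expected in every line. Recovery was therefore not measured for genes near 0 or silent in a line. The share of false calls holds only where few genes change, unlike in these data.

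The alternatives were DESeq2-type size factors, library totals, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on the deposited log2 RPKM values, each line fitted alone, an additive model for the average, non-robust estimation, replicate blocks shared by the lines or within each line, and each library left out in turn. Counts thinned to equal depth were an alternative chosen after seeing the data. The log2 RPKM values served only as that alternative.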

Results

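The data are RNA sequencing counts from 4 multiple myeloma lines (malignant plasma cells in culture) in which IRF4, a transcription factor of plasma cells, was targeted by CRISPR. The question, named in the study's title, is whether IRF4 holds down the pro-apoptotic genes BMF and BCL2L11 and so keeps myeloma cells alive. The other genes show what else changed with the IRF4 guide. With a single IRF4 guide and time point, direct effects of IRF4 loss cannot be told apart from later or off-target ones. Each line had 3 libraries with the IRF4 guide and 3 with the EV guide, except MM1S with 2 EV libraries. Totals ran from 8390849 to 27406220 counts in H929, from 6907390 to 28486960 in MM1S, from 8550347 to 27846502 in OPM2 and from 8974460 to 26133179 in RPMI-8226. Changes are log2 fold changes of the IRF4 guide over the EV guide, given ± SE. Every line is compared with its own EV libraries.

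IRF4 (Entrez 3662, chromosome 6, 391752 to 411443 on GRCh38) fell in each line. Its level with the IRF4 guide was 736 ± 142 CPM (SD, n = 3) against 2199 ± 19.1 (n = 3) in H929, and 265 ± 32.3 (n = 3) against 683 ± 58.6 (n = 2) in MM1S. It was 1039 ± 252 against 1640 ± 361 in OPM2 and 210 ± 34.7 against 451 ± 37.7 in RPMI-8226 (n = 3 each). The log2 fold changes were -1.58 ± 0.18, -1.37 ± 0.20, -0.66 ± 0.18 and -1.10 ± 0.18 in that order, and -1.18 ± 0.09 on average (adjusted p = 4.19e-09). In OPM2, where the adjusted p was 0.00675, the ranges overlapped (890 to 1331 against 1319 to 2031 CPM), but within each replicate number IRF4 was lower (890 against 1570, 1331 against 2031 and 897 against 1319), and the fall was also called with the replicate block within each line. The change differed between lines (adjusted p of the F test 0.0317). IRF4 mRNA measures neither the protein nor how many alleles were edited, so remaining transcripts may carry edits.

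BMF (Entrez 90427, chromosome 15, 40087890 to 40108879), a BH3-only activator of apoptosis that binds and blocks the pro-survival BCL2 proteins, rose in all 4 lines, 5.43-fold on average (2.44 ± 0.07, adjusted p = 1.50e-18). Its level went from 46.7 ± 6.37 to 464 ± 34.5 CPM in H929, from 236 ± 12.5 to 821 ± 27.3 in MM1S, from 72.3 ± 9.94 to 686 ± 42.3 in OPM2 and from 56.6 ± 7.33 to 152 ± 31.1 in RPMI-8226. The rise was 9.83-fold in H929 and 9.47-fold in OPM2, against 3.48-fold in MM1S and 2.68-fold in RPMI-8226, and differed between lines (F test adjusted p = 3.78e-09). BCL2L11 (Entrez 10018, chromosome 2, 111120914 to 111168445), which encodes the BH3-only protein BIM, rose 1.82-fold on average (0.86 ± 0.04, adjusted p = 8.13e-17). Its rise was 0.79 ± 0.08 in H929, 0.77 ± 0.09 in MM1S, 0.85 ± 0.08 in OPM2 and 1.04 ± 0.08 in RPMI-8226, and a difference between lines was not detected (adjusted p = 0.150).

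**Figure D1:**
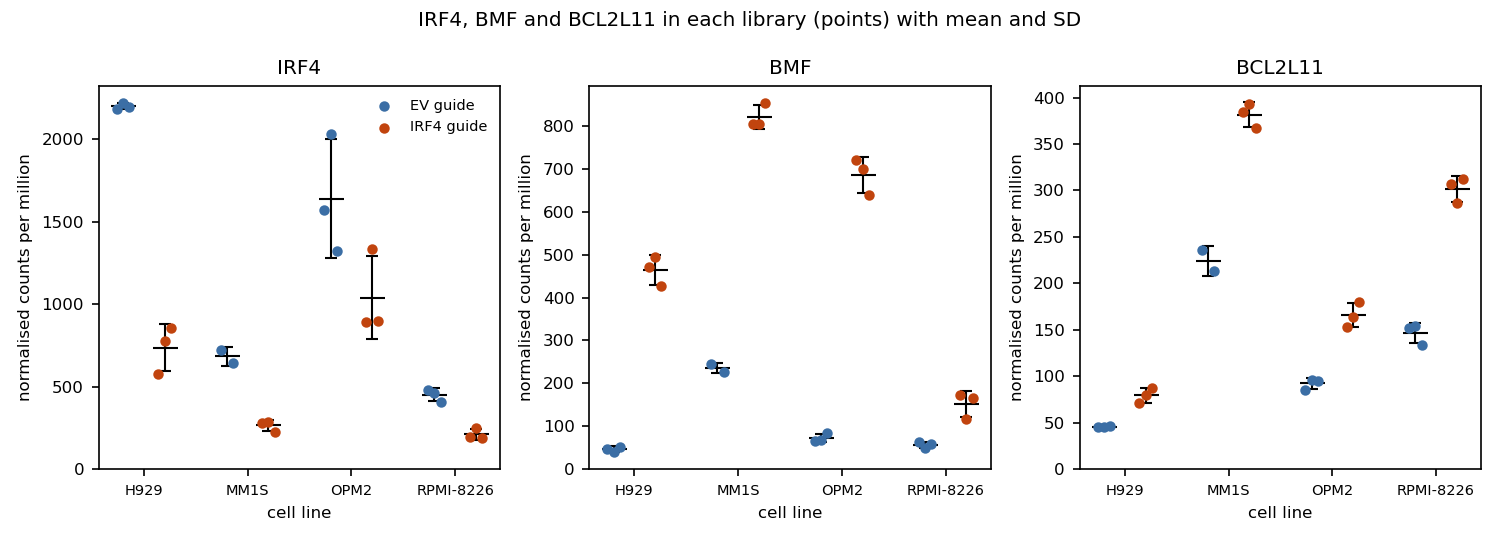
Levels of IRF4, BMF and BCL2L11 in normalised counts per library (vertical axes, CPM) in the 4 lines (horizontal axes); points are libraries with the EV guide (blue) or the IRF4 guide (orange), with mean and SD. Every IRF4-guide library lay above every EV library of its line for BMF and BCL2L11, while IRF4 overlapped between the guides in OPM2.

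Other members of the BCL2 family moved in both directions. BBC3, which encodes the BH3-only protein PUMA, rose by 1.36 ± 0.11 on average (adjusted p = 3.11e-11), most in H929 (2.03 ± 0.19) and MM1S (2.26 ± 0.22). BAX, a pore former of the mitochondrial membrane, rose by 0.53 ± 0.05 on average, with 1.05 in MM1S and 0.12 in OPM2 (not called), and both genes differed between lines (F test adjusted p = 1.01e-05 and 1.37e-05). HRK was at least 4.39-fold higher in MM1S, where the EV group had 0 counts, and PMAIP1 (NOXA) fell by 0.59 on average. Among the pro-survival genes BCL2 rose in H929 (1.12) and RPMI-8226 (0.42), BCL2L1 rose in H929 (0.28) and MM1S (0.70) and fell in RPMI-8226 (-0.21), and MCL1 rose in H929, MM1S and OPM2 (0.49, 0.51 and 0.28), each with a difference between lines. Of the 10 tested pro-apoptotic members, 5 rose and 3 fell on average (camera adjusted p = 0.0214, up), but the call was lost with an estimated correlation (adjusted p = 0.116) and with the replicate number as a block shared by the lines or within each line (0.129 and 0.132). Of the 5 tested pro-survival members, 3 rose, and the list was not called (adjusted p = 0.234).

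Some single-line calls of these genes rest on few libraries. The calls of BBC3 (0.54, adjusted p = 0.0243), BAX (0.25, adjusted p = 0.0484), PMAIP1 (-0.31, adjusted p = 0.0469) and BCL2L1 in RPMI-8226 were near the threshold and each ended under several alternatives. Those of BBC3 and BCL2L1 ended without single RPMI-8226 libraries, and those of BAX and PMAIP1 also without single libraries of other lines, with BBC3 at 0.28 (adjusted p = 0.224) without IRF4 replicate 2 and BAX at 0.16 (adjusted p = 0.284) without IRF4 replicate 1. MCL1 in OPM2 (adjusted p = 0.0402) was lost without any of 5 OPM2 libraries, and BCL2L1 in H929 without IRF4 replicate 1 (0.14, adjusted p = 0.167). BBC3 in OPM2, at 0.60 ± 0.26 (adjusted p = 0.0669), was called with the replicate block within each line (0.63, adjusted p = 0.0272). Among caspases and death receptors, CASP8, the initiator caspase of death receptors, rose in all 4 lines (0.65 ± 0.04 on average), and FAS, itself a death receptor, rose by 0.72 ± 0.08. Of the 16 tested members of that list 7 rose and 4 fell, and it was not called (adjusted p = 0.219).

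On the average of the 4 lines, 9505 of 16468 tested genes changed, 5369 higher and 4136 lower, of which 1517 and 153 by at least 2-fold. Of the changed genes 56.5% were higher, against 46.2% on the deposited log2 RPKM values. In all 4 lines 1476 genes changed the same way, 846 higher and 630 lower, against 46.8 and 19.4 that independent calls in the 4 lines would give, and 57.3% of the 1476 were higher, against 44.7% with each line fitted alone. Among the largest shared rises were those of GSN (gelsolin, which severs actin filaments), by 1.81 in MM1S to 5.68 in H929 (adjusted p = 2.24e-13 on average), and TMEM229B, 12.2-fold (3.61 ± 0.09, adjusted p = 1.42e-22). DDX60, an antiviral helicase, rose 11.2-fold, MYO1F, a myosin of white blood cells, 10.3-fold, and C3AR1, a complement receptor, 10.1-fold. BCL6, the repressor that defines germinal centre B cells, rose 7.98-fold (3.00 ± 0.14, adjusted p = 3.41e-17). MYO7A, another myosin, also rose in all 4 lines and was at least 55.4-fold higher in OPM2, where the EV group had 0 counts.

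The largest shared falls were in MYB, a proto-oncogene of blood progenitors, at -2.12 ± 0.11 (adjusted p = 5.80e-12), and KLF2, a transcription factor of lymphocyte homing, at -2.08 ± 0.17 (adjusted p = 7.65e-09). SLC7A2, an amino acid transporter, fell by 1.82 on the log2 scale and TNFRSF17, which encodes the plasma cell receptor BCMA, by 1.61, in RPMI-8226 by 2.74. TERT, the catalytic subunit of telomerase, fell by 1.51 and CAV1, a coat protein of caveolae, by 1.44. For KLF2, TERT and CAV1 no difference between lines was detected (adjusted p = 0.227, 0.0877 and 0.241). Genes silent in a line could not be called on the average, so these rankings leave them out.

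**Figure D2:**
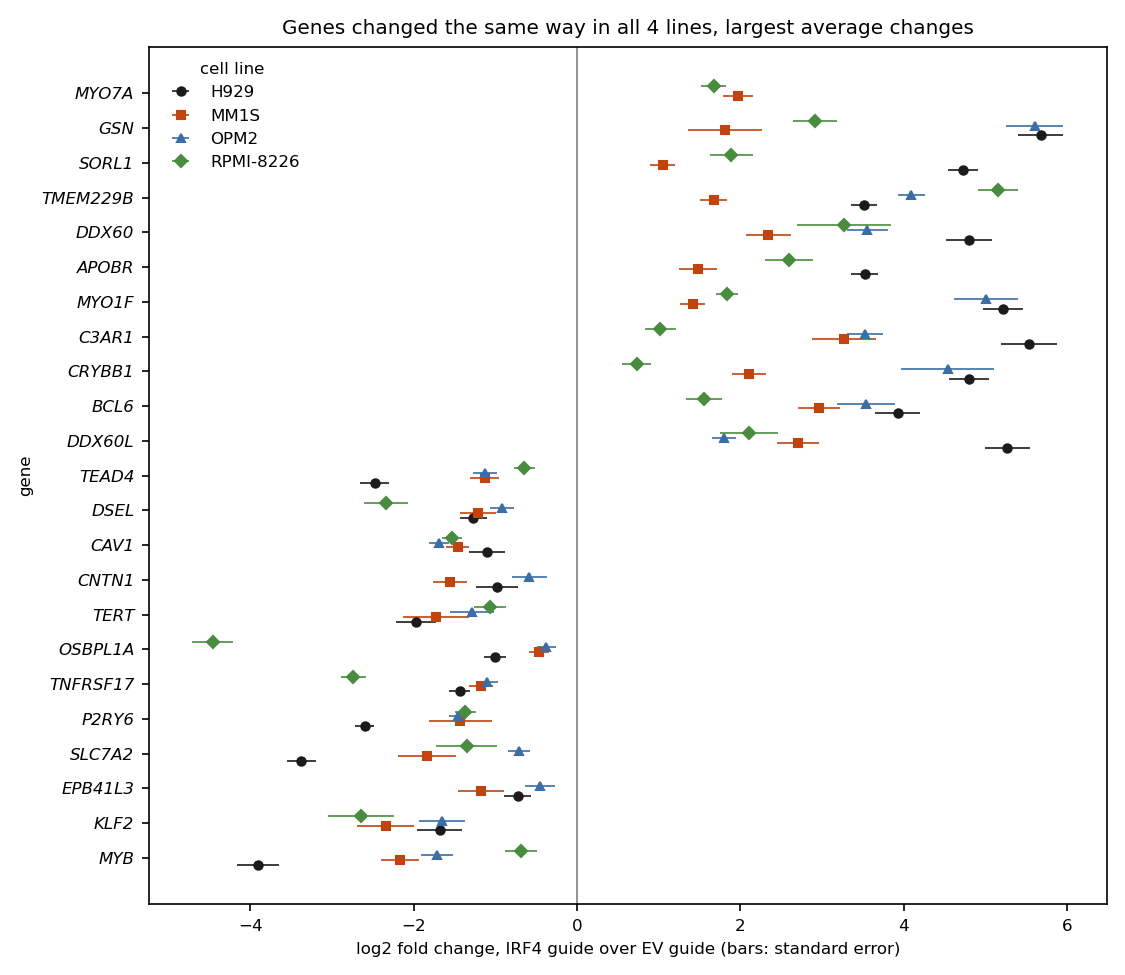
Log2 fold change of the IRF4 guide over the EV guide (horizontal axis; bars are the SE) for genes among the largest shared rises and falls (vertical axis), with 1 symbol per cell line. GSN ran from 1.81 in MM1S to 5.68 in H929, and lines in which a group had 3 counts or fewer are not drawn.

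On the average of the 4 lines, plasma cell genes fell and B cell genes rose. PRDM1, the master regulator of plasma cells, fell in all 4 lines (-0.57 ± 0.04 on average), although its call in H929 (-0.26, adjusted p = 0.00588) was lost on the deposited log2 RPKM values (-0.17, adjusted p = 0.0761). ELL2, an elongation factor of immunoglobulin secretion, also fell in each line (-0.58 ± 0.05 on average). POU2AF1, a coactivator of immunoglobulin genes, fell in H929, MM1S and OPM2 but was at 0.07 in RPMI-8226 (F test adjusted p = 1.98e-07). Of 19 tested plasma cell identity genes 13 fell and 3 rose on average (camera adjusted p = 0.000320, down), with adjusted p = 0.177 with an estimated correlation. The list was called in OPM2 and RPMI-8226 (camera adjusted p = 8.06e-09 and 0.00164, with estimated correlations at 0.135 and 0.314). It was not called in H929 or MM1S (0.0757 and 0.0701), except with the replicate block within each line (0.0306 and 0.0350). In the B cell programme, 10 of 17 tested genes rose and 1 fell (adjusted p = 0.00225; adjusted p = 0.135 with an estimated correlation). ID3, an inhibitor of E proteins, rose by 1.69 ± 0.07 and SPIB, an ETS factor of B cells, by 2.13 ± 0.12, each in all 4 lines.

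Of the 15 genes tied to IRF4 in myeloma, 12 fell and 1 rose on average (adjusted p = 6.21e-09), and this list was among the 4 called with an estimated correlation (adjusted p = 0.0442). CDK6, a kinase of the G1 phase, fell by 0.71 and SUB1, a transcriptional coactivator, by 0.81 in log2 terms, each in all 4 lines. MYC, the growth-promoting transcription factor, went from 421 to 179 CPM in H929, from 468 to 236 in OPM2 and from 1151 to 601 in RPMI-8226. In MM1S it went from 569 to 758 CPM, a rise of 0.42 ± 0.11 (adjusted p = 0.00418) that was not called without MM1S EV replicate 3 (0.37, adjusted p = 0.0621). The difference between lines for MYC had an adjusted p of 2.85e-09. In MM1S 15 of the 30 MYC target genes fell, 16 when adjusted over the list alone (camera adjusted p = 1.34e-05; adjusted p = 0.357 with an estimated correlation).

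Genes of growth and division fell. All 30 MYC target and nucleolar genes fell on average (median -0.71, adjusted p = 1.86e-21; adjusted p = 0.0852 with an estimated correlation). NOLC1, a nucleolar chaperone of ribosome assembly, fell by 0.81 and PA2G4, a growth-linked nucleolar protein, by 0.87, each in all 4 lines. All 28 G1/S and DNA replication genes fell on average (median -0.81, adjusted p = 1.52e-23; adjusted p = 0.0651 with an estimated correlation), with MCM10 at -1.09 ± 0.05 and CDC6 at -1.14 ± 0.05, which both load the replication machinery. Among G2/M and mitosis genes 26 of 28 fell (adjusted p = 5.99e-09; adjusted p = 0.196 with an estimated correlation), with cyclin A (CCNA2) at -0.67 ± 0.05 and the mitotic kinase AURKB at -0.69 ± 0.06. Of 32 proteasome genes 29 fell (median -0.36, adjusted p = 8.28e-11; adjusted p = 0.174 with an estimated correlation), with PSMD12, a subunit of the regulatory particle, at -0.69 ± 0.04. Of 14 cytosolic heat shock genes 11 fell (adjusted p = 6.22e-07; adjusted p = 0.135 with an estimated correlation), with HSPD1, a chaperonin of mitochondria listed with them, at -0.92 ± 0.04 and HSP90AA1 at -0.81 ± 0.05.

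The cell cycle genes differed between the lines. In H929 and MM1S all 28 G1/S genes fell, in OPM2 23 fell, and in RPMI-8226 2 rose, 5 fell and 21 were not called, with medians of -1.37, -1.08, -0.50 and -0.12. The list was called in the first 3 lines (adjusted p = 1.52e-24, 3.79e-38 and 1.26e-08), with estimated correlations at adjusted p = 0.0647, 0.0632 and 0.236. It was not called in RPMI-8226 (adjusted p = 0.182), where it was called without IRF4 replicate 2 (adjusted p = 0.0248, down). G2/M genes fell 28, 22 and 15 times in the first 3 lines (adjusted p = 1.36e-12, 5.67e-11 and 0.00119, with estimated correlations at adjusted p = 0.141, 0.214 and 0.434), while in RPMI-8226 6 rose and 1 fell (adjusted p = 0.274). Adjusted over the list alone, 24 G1/S genes fell in OPM2, 23 and 17 G2/M genes fell in MM1S and OPM2, and 5 G2/M genes rose in RPMI-8226. MCM10, at -2.12 in H929 and -0.22 in RPMI-8226, differed between lines (adjusted p = 1.47e-11), as did CCNA2 (-1.40 and -0.11, adjusted p = 1.93e-08).

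Metabolic genes fell in several groups. Sterol and fatty acid synthesis fell in 23 of 27 genes (median -0.67, adjusted p = 5.00e-12; adjusted p = 0.0924 with an estimated correlation). FADS1, a fatty acid desaturase, fell by 1.30 on average (adjusted p = 3.53e-18) and HMGCS1, an enzyme of the mevalonate pathway, by 0.77, each in all 4 lines. In glycolysis 14 of 20 genes fell and 4 rose (adjusted p = 0.00307; adjusted p = 0.382 with an estimated correlation), with lactate dehydrogenase LDHA at -0.89 ± 0.07 and PDK1, which restrains pyruvate oxidation, at -0.82 ± 0.05. In oxidative phosphorylation 12 of 24 genes fell and 1 rose (median -0.12, adjusted p = 0.0241, and 0.488 with an estimated correlation). SDHB of complex II was at -0.43 ± 0.04. The list was not called in RPMI-8226 (camera adjusted p = 0.139) or MM1S (0.870), where 4 genes rose and 1 fell. In the ATF4 and amino acid response 12 of 22 genes fell and 2 rose (adjusted p = 0.00227; adjusted p = 0.382 with an estimated correlation), with the arginine transporter SLC7A1 at -0.80 ± 0.04 and the mitochondrial folate enzyme MTHFD2 at -0.50 ± 0.04. In the unfolded protein response 14 of 22 fell and 6 rose (adjusted p = 0.00854, and 0.388 with an estimated correlation). Of the single lines, OPM2 alone had this list called (camera adjusted p = 1.98e-06, and 0.210 with an estimated correlation). In H929, MM1S and RPMI-8226 the camera adjusted p was 0.238, 0.210 and 0.177. SEL1L, of the degradation complex of the endoplasmic reticulum, fell by 0.73 on average but was at 0.01 in RPMI-8226 (F test adjusted p = 7.35e-10), and the disulfide isomerase PDIA6 fell by 0.40.

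Interferon and MHC class I presentation genes rose. Of 28 interferon-stimulated genes 25 rose on average and none of the others was called lower (median 1.16, adjusted p = 8.98e-08; adjusted p = 0.0442 with an estimated correlation). DDX58, the RNA sensor RIG-I, rose by 1.62 ± 0.09 and the ubiquitin-like modifier ISG15 by 1.60 ± 0.10, with ISG15 at 3.63 in OPM2 and 0.40 in RPMI-8226 (F test adjusted p = 8.75e-09). Of 8 interferon regulatory factors other than IRF4, 7 rose (adjusted p = 0.00252; adjusted p = 0.0442 with an estimated correlation), with IRF1 at 0.77 ± 0.04 and IRF9 at 1.26 ± 0.10. In RPMI-8226, where 3 rose and 1 fell, that list was not called (camera adjusted p = 0.259). IRF1 rose by 0.66 to 0.81 across the lines, with no difference detected (adjusted p = 0.615). In MHC class I presentation 12 of 15 genes rose and 1 fell (median 0.33, adjusted p = 0.000320; adjusted p = 0.116 with an estimated correlation), with the peptide-loading chaperone TAPBP at 0.84 ± 0.04. This list was not called in MM1S (camera adjusted p = 0.182). NF-kB targets rose in 13 of 20 cases (adjusted p = 0.000146; adjusted p = 0.0852 with an estimated correlation), with the NF-kB subunit RELB at 0.99 ± 0.06 and its partner BCL3 at 1.52 ± 0.08. They were not called in H929 or MM1S (camera adjusted p = 0.0832 and 0.0931). In MM1S they were called with the replicate block shared by the lines or within each line (0.0268 and 0.0164), and in H929 without EV replicate 3 (0.0398).

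Lysosomal, adhesion and signalling genes also rose. In lysosome and autophagy 19 of 25 genes rose and 1 fell (median 0.49, adjusted p = 6.30e-09; adjusted p = 0.0442 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose by 0.67 ± 0.04, and the lysosomal protease CTSA by 0.93 ± 0.04, from 2.30 in H929 to 0.21 in RPMI-8226 (F test adjusted p = 7.14e-14). Of 19 adhesion and homing genes 12 rose and 4 fell, and 5 fell when adjusted over the list alone (camera adjusted p = 0.0343). That call was lost with an estimated correlation (adjusted p = 0.179) and with a shared or within-line replicate block (0.0733 and 0.0989). The leukocyte integrin ITGAL rose by 1.43 ± 0.07 and ICAM3, which binds it, by 0.89 ± 0.04. Of 24 cytokine receptor and signalling genes 14 rose and 5 fell (adjusted p = 0.00227; adjusted p = 0.164 with an estimated correlation), with the kinase JAK1 at 0.73 ± 0.04 and the factor STAT3 at 0.76 ± 0.05.

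Targets of p53 rose in 17 of 23 cases and fell in 3, and 18 rose when adjusted over the list alone (median 0.72, adjusted p = 5.79e-05; adjusted p = 0.116 with an estimated correlation). SESN1, a stress-induced regulator of growth, rose in all 4 lines (0.92 ± 0.06), while FDXR, a mitochondrial reductase, rose by 1.57 in H929 and 1.74 in MM1S against 0.15 in OPM2 and 0.55 in RPMI-8226 (F test adjusted p = 8.67e-08). The DNA repair gene XPC rose by 0.92, 0.98 and 0.29 in H929, MM1S and RPMI-8226 and was at 0.05 in OPM2 (F test adjusted p = 4.28e-07). The members that fell, chosen for naming after their values were seen, were MDM2, the negative regulator of p53, at -0.25 ± 0.06, the survival factor TRIAP1 at -0.32 ± 0.05 and the nuclease AEN at -0.34 ± 0.09. CDKN1A, the cell cycle inhibitor p21, also chosen after its values were seen, rose in H929, MM1S and OPM2 (1.21, 2.05 and 0.79) and fell in RPMI-8226 (-0.71). The list was called in H929 (adjusted p = 0.000201) and MM1S (adjusted p = 6.59e-10), with estimated correlations at adjusted p = 0.154 and 0.0687. In RPMI-8226 its adjusted p of 0.0148 (0.347 with an estimated correlation) went to 0.0769 without IRF4 replicate 1 and 0.0665 without EV replicate 3. In OPM2 the list had an adjusted p of 0.106 (0.447 with an estimated correlation) and one of 0.0344 with the replicate block within each line.

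**Figure D3:**
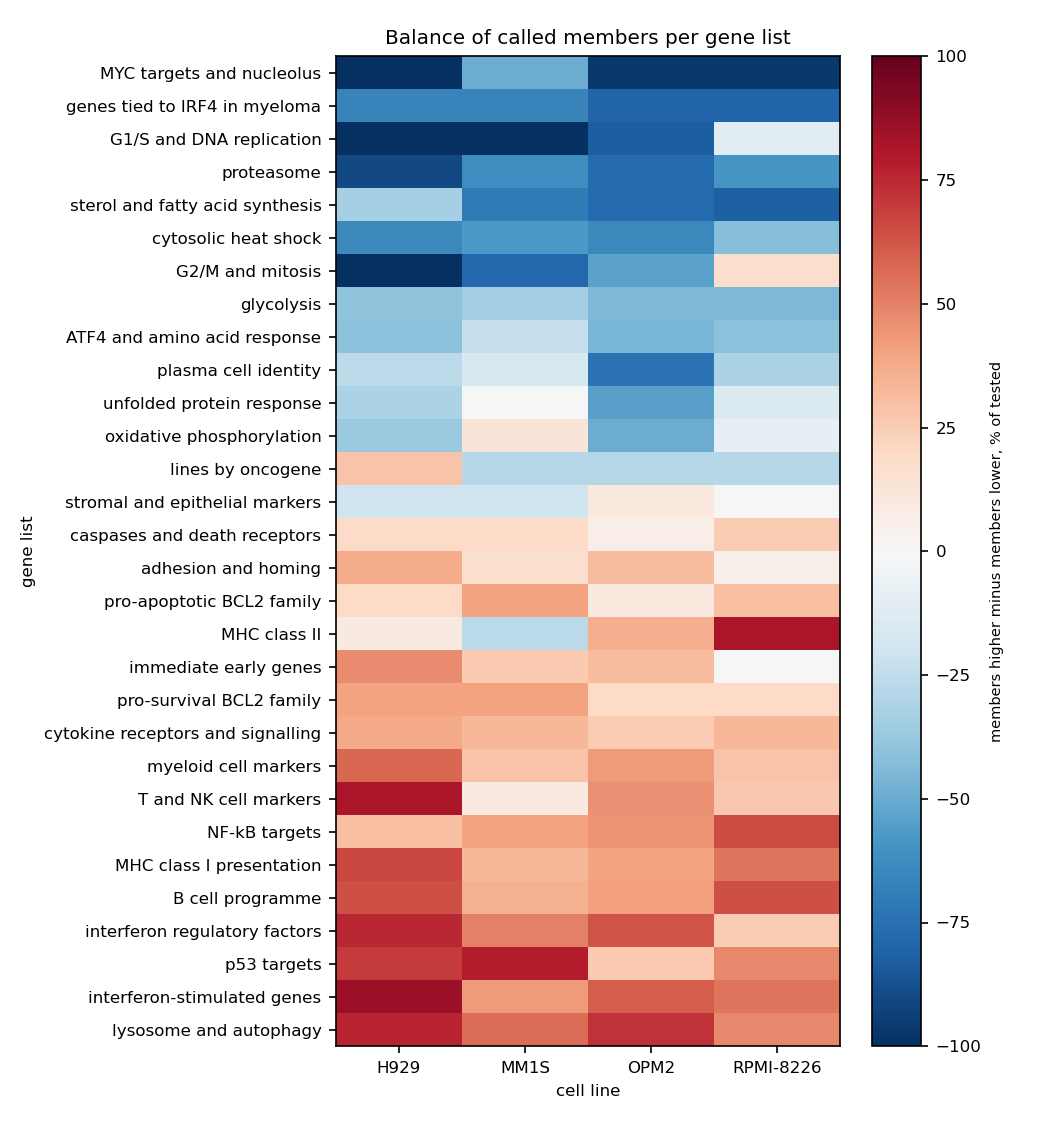
Share of tested members higher minus share lower with the IRF4 guide (color, % of tested members) for the 30 tested gene lists (vertical axis) in the 4 lines (horizontal axis). MYC targets and IRF4-tied genes were lower on balance in every line, while G2/M genes were at -100% in H929 and above 0 in RPMI-8226.

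On the average, the counts above of called members over all genes tested equalled those adjusted over the list alone for every list except adhesion and homing, p53 targets and MHC class II. Members silent in a line stand among those tested but cannot be called on the average. Camera called 22 of the 30 lists, and 4 of these held with an estimated correlation. Per line it called 20 lists in H929, 16 in MM1S, 22 in OPM2 and 18 in RPMI-8226, of which 0, 0, 0 and 2 held. The 2 in RPMI-8226 were NF-kB targets, with 14 of 20 genes higher (adjusted p = 2.50e-07), and the oncogenes that mark lines, with 4 of 7 lower and 2 higher (adjusted p = 0.00164), both at 0.0452 with an estimated correlation.

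In H929, 9706 genes changed, 5411 higher and 4295 lower, with 2713 and 1150 of these by at least 2-fold. The share higher was 55.7%, against 45.6% on the deposited log2 RPKM values and 49.0% with the line fitted alone. The largest rises were in GZMB, the cytotoxic protease granzyme B, at 97.0 ± 22.2 CPM against 0.0710 ± 0.0629 (9.96 ± 0.30, adjusted p = 1.39e-18), S100A9, a calcium-binding protein of myeloid cells (7.93 ± 0.40), CD7, a T and NK cell receptor (7.57 ± 0.40), and DMBT1, a mucosal scavenger receptor (7.15 ± 0.26). These fitted changes rest on EV levels near 0 and are rough in size. Besides MYB (-3.90) and SLC7A2 (-3.37), the largest falls were in MAP1B, a microtubule protein, at -3.35 ± 0.14 and AMPD1, an AMP deaminase, at -3.24 ± 0.24. Markers of T and NK cells rose in 9 of 11 tested genes (adjusted p = 2.84e-07; adjusted p = 0.0647 with an estimated correlation), among them CD3E (2.90 ± 0.15). Myeloid markers rose in 5 of 7 and fell in 1 (adjusted p = 0.00645; adjusted p = 0.0647 with an estimated correlation), a call lost with the replicate block within each line (0.0528).

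In MM1S, 5693 genes changed, 3193 higher and 2500 lower. The share higher was 56.1%, against 48.2% on the deposited log2 RPKM values and 48.0% with the line fitted alone. KRT15, an epithelial keratin, rose 30.7-fold (4.94 ± 0.45), MMP9, a matrix protease, 18.2-fold (4.19 ± 0.36) and C3AR1 9.64-fold. GPRC5D, a surface receptor of plasma cells, fell by 3.27 ± 0.23 on the log2 scale, CAV2, a partner of CAV1, by 2.89, the neurotrophin receptor NTRK2 by 2.83 and DKK1, a Wnt inhibitor that myeloma cells secrete, by 2.60. With 2 EV libraries this line had the least precise contrasts, and 3810 genes changed without EV replicate 2.

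In OPM2, 7156 genes changed, 3829 higher and 3327 lower, 1744 and 215 of them by at least 2-fold. DMBT1 rose by 8.49 ± 0.33, CD180, a B cell receptor of the Toll-like family, by 7.11 ± 0.65, and IL2RG, the common chain of several cytokine receptors, by 5.72 ± 0.44, all from EV levels near 0 and so rough in size. UNC13C, a vesicle priming protein, fell by 2.43 ± 0.23, NTRK2 by 2.05 and the drug transporter ABCG2 by 1.93. Scaled by library totals, 66.7% of the changed genes were higher, against 53.5% here and 47.7% on the deposited log2 RPKM values. The cytokine receptor list (adjusted p = 0.0342; adjusted p = 0.332 with an estimated correlation) was lost with the shared replicate block (0.0662) and without IRF4 replicate 2, EV replicate 1 or RPMI-8226 IRF4 replicate 2 (0.0785, 0.0555 and 0.0632). The plasma cell list fell in 14 of 19 genes, 15 when adjusted over the list alone (camera adjusted p = 8.06e-09; adjusted p = 0.135 with an estimated correlation).

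In RPMI-8226, 5587 genes changed, 3162 higher and 2425 lower. The share higher was 56.6%, against 65.1% under library totals and 48.2% on the deposited log2 RPKM values. TMEM229B rose 35.7-fold (5.16 ± 0.24), PTPRC, the leukocyte phosphatase CD45, 25.7-fold (4.68 ± 0.40) and LTB, the cytokine lymphotoxin beta, by 3.91 ± 0.37 in log2 terms. GJA1, the gap junction protein connexin 43, fell by 6.38 ± 0.25, DPYSL3, a cytoskeletal regulator of neurons, by 5.33 ± 0.20 and PLS3, an actin-bundling plastin, by 4.15 ± 0.14, each on the log2 scale.

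The change differed between lines for 7899 genes (48.0%), and 1329 genes (8.06%) were called in opposite directions in at least 2 lines, 1328 of them with the difference itself called. DPYSL3 rose in H929 (1.57) and fell in RPMI-8226 (-5.33), with the smallest p of the difference (adjusted p = 2.50e-17). GJA1 rose in MM1S (0.73) and was higher in H929, by 12.1-fold (12 against 1 counts, interval 1.79 to 518), and in OPM2, by 117-fold (303 against 2 counts, interval 32.0 to 967), while it fell in RPMI-8226. MBP, known from myelin and also made in blood cells, rose in H929 (2.69) and MM1S (0.57) and fell in OPM2 (-0.30). The guanine exchange factor ARHGEF3 rose in the first 3 lines (2.47, 0.66 and 1.69) and fell in RPMI-8226 (-0.70), and the lactate exporter SLC16A3 rose in the same 3 (3.63, 0.67 and 0.91). RUNX3, a lymphoid transcription factor, rose in H929 (2.69) and OPM2 (1.33), LCP1, the plastin of white blood cells, in H929 (1.90) and OPM2 (3.87), and PARP14, a mono-ADP-ribosylase, by 3.50, 0.35, 3.32 and 0.31 in the 4 lines.

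The directions of calls were shared more than chance gives for every pair of lines. H929 and OPM2 shared the most, with 2843 genes higher in both (1258 by chance), 2615 lower in both (868) and 262 opposite (2092), so that 95.4% of genes called in both went the same way. MM1S and RPMI-8226 shared the fewest, with 1272 higher in both (613 by chance), 854 lower in both (368) and 431 opposite (950), or 83.1% the same way. The other 4 pairs lay between 85.7 and 92.0%, and Spearman correlations of the changes across genes (not independent replicates) ran from 0.306 for MM1S and RPMI-8226 to 0.622 for H929 and OPM2.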

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

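The 4 gene-count regroupings (average, H929, OPM2 and RPMI-8226) were planned before results were seen. So were the test of the difference between lines and the list calls within a line with a library left out. Every other test in this part was chosen after results were seen. Genes below are named because the test of the difference between lines had an adjusted p under 0.05, and spans are in log2 units between the highest and lowest line with more than 3 counts in both groups.

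The log2 change of the G1/S genes was higher in RPMI-8226 than the mean change of the other 3 lines. The median difference was 0.85 (camera adjusted p = 2.83e-33, and 0.118 with an estimated correlation). For the G2/M genes it was 0.61 (camera adjusted p = 8.74e-20, and 0.168 with an estimated correlation). RPMI-8226 IRF4 replicate 2, without which the G1/S list was called lower in that line (0.0248), moved this difference little (0.78 for G1/S and 0.60 for G2/M without it), and of the 30 lists 10 were called in the difference and 0 with an estimated correlation. A scaling offset would shift all genes alike, but the G1/S difference was 0.87 once the median difference of all genes was taken off, which argues against it. A smaller fall of IRF4 mRNA could also leave the cell cycle alone. By point estimate IRF4 fell less in RPMI-8226 than in H929 and MM1S, where all G1/S genes fell, which goes with this explanation. Those differences were not tested. Against OPM2 IRF4 fell by 0.44 more in RPMI-8226 (difference -0.44 ± 0.18 with the OPM2 samples paired, ± 0.26 unpaired). With replicate blocks shared by the lines and within each line it was -0.45 ± 0.21 and -0.45 ± 0.13. The difference was beyond 2 SE in each blocked fit but not in the unpaired one. With the OPM2 samples paired, as taken here, this argues against a smaller fall of IRF4 mRNA in the comparison with OPM2. In the comparison with H929 and MM1S a smaller fall stays undecided. IRF4 protein was not measured, the line itself was the only biological group the design held, and what in it matters was not tested.

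In H929 the T and NK cell markers summed to 274 ± 24.6 CPM against 17.6 ± 1.91 (n = 3 each), with CD3E at 107 ± 10.8 against 14.1 and PRF1 at 41.8 ± 8.73 against 1.80. T or NK cells mixed into the cultures would bring their general genes along with GZMB. The median gain of CD2, CD3D, CD3G, TRAC, LCK and NKG7 was 0.723% of the GZMB gain (0.311 to 1.07% over 3 libraries). This set was chosen after values were seen, so its median cannot decide on such cells. It left out CD3E, PRF1 and GNLY, which gained 92.6, 40.0 and 12.1 CPM. It also left out CD4, CD8A and KLRD1, which gained 0.0161 CPM or less. GZMB gained 96.9 CPM and CD3E 92.6, against 8.47 for NKG7, 4.28 for TRAC, 0.744 for CD3D, 0.630 for CD3G, 0.492 for CD2 and 0.0322 for LCK. A general gain of low-level genes was set against 10000 random lists matched on EV level. The list's median, with low counts at their bound, lay at percentile 100. It was 3.75 against 2.08 at the top of the middle 95%, which argues against such a general gain. T cells that brought the CD3E gain of 92.6 CPM would bring the other CD3 chains too. The gains of 0.744 for CD3D and 0.630 for CD3G argue against T cells as the source of CD3E. For the other genes mixed-in cells remain open. Activation of these genes in the H929 cells also remains open, with no test here.

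Targets of p53 rose more in H929 and MM1S than in OPM2 and RPMI-8226, a grouping chosen after the values were seen, by a median of 0.41 (camera adjusted p = 1.20e-05), with 12 genes higher, 1 lower and 10 not called. Known p53 status of these lines could explain this, but the adjusted p was 0.238 with an estimated correlation, so that stays undecided. The changes of OPM2 were multiplied by 1.31 to bring their median size to the mean of those of H929 and MM1S, which were not scaled. A median of 0.58 was then left against OPM2 (0.14 to 0.83 over resampled members). Against RPMI-8226, multiplied by 1.73, it was 0.22 (-0.59 to 0.56). Resampled members carry no spread between libraries and treat the genes as independent. Larger changes of all genes in H929 and MM1S therefore stay undecided against either line. DNA cutting by the IRF4 guide could raise p53 targets in every line. It would give the 0.41 only if the lines answered cutting unequally. Cutting was undecided, since whether the EV guide cuts was not given in the sources used here. In the same contrast the G1/S genes differed by -0.98 (2.42e-45; 0.0352 with an estimated correlation), with 7 lists called and 1 with an estimated correlation.

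Regrouped libraries show how often counts this large arise under other groupings, some of which keep whole lines split by guide. Of 100 splits within lines, 1 (the real one) reached the 9505 genes on the average, with 6233 as the highest other, from a split that mirrors 2 whole lines. For the 1476 genes shared by all lines the share was 1 of 100 (highest other 0), and for the 22 lists on the average 1 of 100 (highest other 20). For the 7899 genes that differed between lines 2 of 100 reached the count, with 8358 as the highest other, from a split with 2 lines as real and 1 mirrored. With 10 splits per line the share cannot go under 0.05, and 1 split reached the gene count in H929 (9706, highest other 2), OPM2 (7156, highest other 1) and RPMI-8226 (5587, highest other 1). The list counts were 20, 22 and 18 there, each reached by 1 split, with 17, 19 and 16 as the highest others, so camera called many lists in regrouped samples as well.

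IRF4 itself spanned 0.92, from OPM2 with the smallest fall to H929, and BMF 1.88, from H929 to RPMI-8226. Among cell death genes the spans were 1.72 for BBC3, 0.93 for BAX, 0.98 for PMAIP1, 0.52 for HRK with MM1S left out, 1.16 for BCL2, 0.91 for BCL2L1, 0.65 for MCL1, 0.99 for CASP8 and 0.89 for FAS. Among genes that moved the same way in all lines, GSN spanned 3.87, TMEM229B 3.48, DDX60 2.46, MYO1F 3.80, C3AR1 4.51 and BCL6 2.37, while MYO7A spanned 0.30 between MM1S and RPMI-8226. Falls spanned 3.22 for MYB, 2.66 for SLC7A2 and 1.64 for TNFRSF17.

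Plasma and B cell regulators spanned less in PRDM1 (0.62), ELL2 (0.65) and POU2AF1 (1.13) than in ID3 (2.04) and SPIB (2.57). MYC spanned 1.65, from MM1S to H929, and CDK6 0.83. Growth genes spanned 1.04 for NOLC1, 0.73 for PA2G4, 1.90 for MCM10, 1.72 for CDC6, 1.29 for CCNA2, 0.97 for AURKB, 0.61 for PSMD12, 1.31 for HSPD1 and 0.43 for HSP90AA1. Metabolic and secretory genes spanned 1.35 for SEL1L, 0.45 for PDIA6, 1.19 for SLC7A1, 1.28 for FADS1, 0.90 for PDK1 and 0.62 for SDHB.

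Interferon and antigen presentation genes spanned 1.72 for DDX58, 3.22 for ISG15, 0.75 for IRF9 and 1.09 for TAPBP, and the MHC class II genes 2.02 for HLA-DMA and 2.37 for CIITA. RELB spanned 0.96, BCL3 2.46, CTSA 2.09, SQSTM1 0.45, ITGAL 2.03, JAK1 1.25 and STAT3 0.89. Targets of p53 spanned 0.72 for SESN1, 1.59 for FDXR, 0.93 for XPC, 0.63 for MDM2, 0.76 for TRIAP1, 1.5 for AEN and 2.76 for CDKN1A. Early response genes spanned 1.51 for BTG1, 0.75 for JUNB and 1.43 for ZFP36.

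Genes with the largest changes of a single line spanned 5.70 for S100A9, 7.10 for CD7, 5.03 for MAP1B, 2.92 for AMPD1, 4.93 for KRT15, 2.67 for GPRC5D, 1.15 for CAV2, 5.43 for NTRK2 and 2.00 for DKK1. In OPM2 and RPMI-8226 such genes spanned 3.71 for CD180, 5.17 for IL2RG, 2.06 for UNC13C, 1.99 for ABCG2, 5.55 for PTPRC, 7.12 for GJA1, 6.90 for DPYSL3 and 4.19 for PLS3. The strongest differences besides these were MBP at 2.99, ARHGEF3 at 3.17, SLC16A3 at 3.85, RUNX3 at 2.92, LCP1 at 4.05 and PARP14 at 3.19. Markers of other cells and of line subgroups spanned 1.70 for VIM, 3.40 for PECAM1, 2.98 for CD3E, 6.27 for PRF1, 2.13 for TRAC, 1.73 for MAF, 0.95 for CCND2 and 1.04 for ITGB7.

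The 11927 genes left out of the tests for low counts also gave a signal, as their summed level was higher with the IRF4 guide in each line. It was 305 ± 27.3 CPM against 170 ± 9.86 in H929 (ratio 1.80), 235 ± 10.8 against 175 ± 15.2 in MM1S (1.35), 258 ± 27.0 against 159 ± 10.4 in OPM2 (1.62) and 269 ± 22.9 against 202 ± 2.85 in RPMI-8226 (1.33).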

How the results depend on the processing

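Thinning to equal depth was the only alternative chosen after results were seen. Of 9403 single-gene values under alternatives, 9289 kept their side of the threshold, 96 lost the call, 18 gained it and 0 reversed. Of the 9289, 6125 came from leaving a library out, often one of another line. A reversal was counted only where a fit called the gene, so uncalled values may have changed sign. Values of the F test have no direction, and genes that an alternative did not test were not counted.

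Lists depended most on the test. With an estimated correlation the called lists numbered 4 on the average and 0 in H929, 0 in MM1S, 0 in OPM2 and 2 in RPMI-8226, against 22, 20, 16, 22 and 18. The tests differed in the correlation between genes, which was preset for all lists or estimated per list. On the average it was estimated at 0.565 for MYC targets, 0.560 for G1/S genes and 0.602 for G2/M genes. These lists lost their calls. It was -0.0269 for the interferon regulatory factors, which kept theirs. Whether the correlation accounts for every lost call was not tested. Fry, which asks another question, called 27 in MM1S.

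With each library left out in turn, the genes changed ran from 8662 to 9810 in H929, 3810 to 5861 in MM1S, 6015 to 7319 in OPM2, 4042 to 5737 in RPMI-8226, 9074 to 9464 on the average, 1091 to 1573 shared by all lines and 7150 to 7993 for the difference between lines. Called lists ran from 22 to 23 on the average, 18 to 21 in H929, 14 to 18 in MM1S, 20 to 22 in OPM2 and 15 to 18 in RPMI-8226. Where a single MM1S EV library remained, it was assumed to vary like the other groups.

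Libraries with the same replicate number correlated at 0.0256 to 0.183 in 11 pairs, 6 of them over 0.1, and all 11 best with their own number. With replicate blocks shared by the lines and within each line the genes changed numbered 10214 and 10339 in H929, 6360 and 6060 in MM1S, 7976 and 8091 in OPM2, 6611 and 6837 in RPMI-8226, 9865 and 9681 on the average, 1914 and 1997 in all lines and 8983 and 8945 for the difference.

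Median log2 changes moved in OPM2 from 0.03 to 0.14 under library totals, and on the log2 RPKM values from 0.10 to -0.07 in H929, 0.03 to -0.08 in OPM2 and 0.11 to -0.03 on the average. The cause was not tested. After thinning, which left 14374 genes to test against 16468, 8427 genes changed in H929, 5359 in MM1S, 5919 in OPM2, 4357 in RPMI-8226, 8356 on the average and 1199 in all lines, with 6763 for the difference, a fall that goes partly with the smaller set of genes.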

Other observations

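The test of MHC class II genes between RPMI-8226 and the other lines was chosen after results were seen, and the other tests in this part were planned. Genes of MHC class II presentation, which plasma cells mostly shut off, had a higher log2 change in RPMI-8226 than the mean of the other 3 lines. The median difference was 1.27 (camera adjusted p = 0.0297), and it was lost with an estimated correlation (adjusted p = 0.390). In RPMI-8226 9 of 11 tested genes rose (camera adjusted p = 0.00219; adjusted p = 0.131 with an estimated correlation), and 1 fell when adjusted over the list alone, with HLA-DMA, which loads peptides, at 1.59 and its transcriptional activator CIITA at 0.81. In MM1S 3 of 11 fell (adjusted p = 0.0358; adjusted p = 0.214 with an estimated correlation), with CIITA at -1.10, and the list was lost without IRF4 replicate 2 (0.0563) or replicate 3 (0.0605) of that line. CIITA also fell in H929 (-1.56) and was at 0.07 in OPM2 (F test adjusted p = 1.28e-07), and its fall on the average (-0.45 ± 0.11, adjusted p = 0.000671) was lost in the additive model (-0.31, adjusted p = 0.221). On the average 6 genes rose and 1 fell, 8 and 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.337).

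Immediate early genes, the first to answer growth and stress signals, rose in 10 of 19 cases and fell in 2 on the average, short of a call (adjusted p = 0.0546), which it gained without any of 7 single libraries (0.0371 to 0.0490). BTG1, an antiproliferative gene, rose in all 4 lines (1.41 ± 0.06 on average), as did the AP-1 subunit JUNB (0.69 ± 0.05), while the mRNA decay factor ZFP36 rose in H929 (1.42) and OPM2 (1.02). In H929 12 of 19 rose and 3 fell (adjusted p = 0.0424; adjusted p = 0.311 with an estimated correlation), a call lost with the shared replicate block (0.0539) and without H929 IRF4 replicate 2, EV replicate 1 or EV replicate 2 or OPM2 IRF4 replicate 1 (0.0531 to 0.0676). In OPM2 8 rose and 2 fell (adjusted p = 0.0224; adjusted p = 0.292 with an estimated correlation), a call lost with the replicate block within each line (0.0531) and without OPM2 IRF4 replicate 2 (0.0764) or EV replicate 1 (0.0555).

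Markers of other cells changed in part. On the average 4 of 11 T and NK cell genes rose (adjusted p = 0.25), 3 of 7 myeloid genes rose (adjusted p = 0.321), and 1 of 10 stromal and epithelial genes rose while 2 fell (adjusted p = 0.337). Of these genes 7, 1 and 3 in turn are silent in a line and cannot be called on the average, so all 4 T and NK cell genes that could be called rose. In OPM2 5 of 11 T and NK cell genes rose (adjusted p = 0.00852; adjusted p = 0.183 with an estimated correlation), with CD3E, a chain of the T cell receptor complex, at 4.25. VIM, an intermediate filament of mesenchymal cells, fell in H929 (-0.44) and MM1S (-1.80), and the adhesion molecule PECAM1 fell in H929, MM1S and OPM2 (-2.27, -1.21 and -1.80) and rose in RPMI-8226 (1.13). Erythroid and megakaryocyte markers summed to 0.343 to 4.14 CPM over the groups, with 3 tested members and no list test.

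Genes that mark subgroups of myeloma lines differed in level between the lines. FGFR3, a growth factor receptor, was at 371 ± 53.8 CPM with the IRF4 guide and 152 ± 22.7 with the EV guide in H929, and at 1414 ± 223 and 2212 ± 227 in OPM2, against 0.450 and 1.12 in MM1S and 4.44 and 2.51 in RPMI-8226. The transcription factor MAF was at 1305 ± 166 and 595 ± 50.9 CPM in MM1S and 887 ± 52.5 and 1345 ± 21.8 in RPMI-8226, against 268 and 178 in H929 and 132 and 69.6 in OPM2. MAF rose in H929, MM1S and OPM2 (0.59, 1.13 and 0.92) and fell in RPMI-8226 (-0.60), with an F test adjusted p of 6.09e-10. Cyclin D2 (CCND2) fell in all 4 lines (-0.82 ± 0.05 on average), and the integrin ITGB7 fell in OPM2 (-0.32) and RPMI-8226 (-1.05). Of the 7 genes 2 rose and 4 fell on the average, and the list was not called (adjusted p = 0.348).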
